A study of Homo sapiens with 49 samples.

How the data were processed

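The samples were 48 regions of melanoma sections in 4 sets of 12, and 1 no-template control, which was not analysed here. Regions were profiled with a whole-transcriptome probe panel, and probe barcodes were sequenced. Per the file headers, the reads were processed with GeoMx NGS Pipeline 2.0.0. The aligner settings behind it are not given in the sources used here, and no genome build applies to probe barcodes as the files hold them.

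The deposited counts of reads at each step, nuclei and probes per target were taken as whole numbers. The gene table after the authors' probe quality control held estimated counts: deduplicated probe counts, whole for all but 1 gene, which had 2 probes whose average need not be whole. These were rounded to whole numbers before any count test. The authors also deposited signal values scaled by each region's upper quartile (Q3) and by its surface area. Sequencing saturation was deposited by the authors as a percent of aligned reads. Other deposited values were the region's position, its surface area and its limit of quantification, whose formula is not stated. The files of counts per probe barcode were not analysed here, as they do not pair barcodes with genes.

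The gene table held 18694 genes and a summary of 138 negative probes. After 23 genes (XIST and Y-linked genes) were left out, 18671 remained, and 18560 passed edgeR's filter on low counts. The total count per region ran from 282220 to 4412732, and 2 regions had a saturation under 60%. Gene names and identifiers were those of the deposited target table. Errors given are the spread between regions or parts, and intervals for counting error were not computed.

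The study's design names areas of keratinocytes, of melanoma cells and of both, but no deposited column names a region's type. So the 3 comparisons planned between region types, the comparison of any other region annotation, and the interaction of set and type were not run, and types were not guessed from marker levels. Instead each list of genes was set against a keratinocyte score and a melanoma score, each the mean over 5 genes of log2 of the scaled count plus 1, with every gene centred over all regions. Genes in a score were taken out of lists set against it.

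Before the data were examined, the gene lists (28), the comparison of sets, the correlations within sets, and the rule for named genes were fixed. The slide parts, the slopes within them and the model of each gene on both scores were chosen after seeing the data, as were their alternatives. Slide parts were made by splitting each set at the widest gap in Y position, which was 71.3% of the range in set A, 63.4% in B, 57% in D, and 37.2% in C, where the next gap was 33.5%. The parts held 4 and 8 regions in A and C and 6 and 6 in B and D. Whether they are tumours is not known.

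Sets were compared with edgeR 4.0.16 (quasi-likelihood F test, upper-quartile factors, R 4.3.3), with Benjamini-Hochberg adjustment and a threshold of 0.05. Slopes of genes came from the same test with the slide part and both scores in the model, and are log2 changes per unit of score. Lists were tested with camera, at a preset and at an estimated correlation between genes, and with fry, in limma 3.58.1. Correlations within sets used permutation tests, two-sided, exact under 10 regions and otherwise with 100000 resamples. Regions were split into clusters wherever a gap in the score exceeded 25% of its range. Slopes within a part were fitted on 1 score alone, and their means over the 8 parts were tested by an exact two-sided sign-flip test and adjusted over the lists and both scores. DESeq2 1.42.0 was used as an alternative. Scores and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

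Named genes were all 12 desmosome genes, and, per set, the 6 genes highest and the 6 lowest by log2 fold change. They had to pass the threshold, lie above the median of tested genes by mean level and differ in the same direction from each of the 3 other sets by the fitted level of the set. The 2 parts of a set were not required to agree. For the slopes the same rule was applied to each score with the same sign in all 8 parts. Of every other list, up to 4 measured members with the highest mean level were eligible. Of the 28 lists, 6 had members that the table did not hold under the name listed, such as LORICRIN and TPSB2. Values of some single list members are not reported here.

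The test between sets over regions and over part sums, the slope on the keratinocyte score, camera on 1 list and the permutation test were tried on simulated data. The counts were drawn from the real means, library sizes and dispersions, with a fixed random set of genes changed. Genes and regions were drawn independently of each other, without the shared slide parts and correlated genes of the real data. So these trials do not show how many false calls the real data hold. The melanoma-score slope, fry, camera with an estimated correlation, the sign-flip test, the test of slopes between sets and DESeq2 were not tried in this way. Between sets of 48 regions, 91.8% of changes of 1 log2 and 99% of changes of 2 were called, with 6 false calls. With counts summed per part, 13.2% of changes of 1 log2, 93.9% of 2 and 100% of 4 were called, with 15 false calls among 152. For slopes on the keratinocyte score, 53% of slopes of 0.1 and 100% of 0.3 were called, with 8 false calls. A desmosome list shifted by 0.5 log2 in set A ranked 3 of 28 and was not called by camera (adjusted p = 0.987), and the size was then raised to 1, where the list ranked 1 (adjusted p = 5.84e-13) with 0 other lists called. The exact permutation test gave p under 0.05 in 5.6% of 1000 simulated pairs of unrelated scores over 8 regions.

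Alternatives were TMM factors, other filters, DESeq2, limma on the authors' Q3 values and on background-subtracted values, covariates for background and for both scores, random blocks, leaving out each set or part, another pseudocount (5), area-normalized values and the median over a list.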

Results

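Whole-transcriptome digital spatial profiling was applied to 48 regions on sections of 8 primary melanomas that had been fixed in formalin and embedded in paraffin. In this assay (GeoMx), photocleavable barcodes on gene probes are released by light from a chosen region and counted by sequencing. The labels put the regions in 4 sets of 12, called A, B, C and D here, and do not say which tumour a region came from or which cell type it held. Antibodies against keratins (PanCK, keratinocytes), S100B and PMEL (melanoma cells) and CD45 (immune cells) guided where the study placed regions. So keratins, PMEL, S100B and CD45 are no finding between regions. How far levels of immune genes reflect that placing was not tested. The total count per region ran from 282220 to 4412732 with a median of 632242, and the median was highest in set C at 2096014 and lowest in set B at 448383.5. Sequencing saturation was 50.3% to 95%, and 9.4% to 58.1% of genes lay above a region's limit of quantification, a deposited value whose formula is not stated. The upper quartile of the counts was a median of 2.07 times the negative-probe level in set B and 3.16 times in set C. Each set split into a part at low and a part at high Y position on its slide, giving 8 slide parts. Whether a part is a single tumour is not stated.

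The first question was with which cell type the transcripts of desmosomes go. Desmosomes are junctions that anchor keratin filaments at the cell membrane. As a mean over 12 genes, their transcripts rose with the keratinocyte score in every slide part, though single genes did not all do so. The keratinocyte score was the mean log2 level of KRT5, KRT14, KRT1, KRT10 and SFN, and the melanoma score that of MLANA, TYR, SOX10, DCT and TYRP1. Over the 8 parts the desmosome score, the mean over 12 genes, rose by 0.50 ± 0.10 (SD) per unit of the keratinocyte score. It did so in 8 of 8 parts (exact sign-flip test, two-sided p = 0.0078, the smallest that 8 parts allow, adjusted p = 0.034). With background subtracted the slope was 0.588 and its adjusted p 0.0547, past the threshold no longer. The adjusted p also depends on how many other lists reach the smallest p values, so this is no sign of a weaker slope.

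Of the 12 desmosome genes, 9 rose with the keratinocyte score, 0 fell and 3 did not pass. The cytolinker DSP rose by 0.87 ± 0.04 (SE) log2 per unit of score, with an adjusted p of 2.39e-24. Among the desmosomal cadherins, DSG1 rose by 0.84 ± 0.03, DSG3 by 0.60 ± 0.06, DSC1 by 0.55 ± 0.08, DSC2 by 0.46 ± 0.07 and DSC3 by 0.36 ± 0.03. Of the armadillo proteins, PKP1 rose by 0.80 ± 0.04, JUP by 0.68 ± 0.04 and PKP3 by 0.63 ± 0.04. Each of these 9 genes had a positive slope in 8 of 8 parts. The slopes of DSG2 (0.07 ± 0.03, adjusted p = 0.132), PKP2 (0.04 ± 0.03, adjusted p = 0.368) and DSG4 (0.02 ± 0.03, adjusted p = 0.758) did not pass. Those genes were also the least detected, with DSG4 above the limit of quantification in 0 of 48 regions, PKP2 in 3 and DSG2 in 10, against 39 for DSP and 45 for DSC3. Adjusted over the list alone, 10 of the 12 passed, DSG2 being the addition. These slopes came from edgeR's quasi-likelihood test over 48 regions with the slide part and both scores in the model. Because regions share tumours, these p-values are too small.

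**Figure D1:**
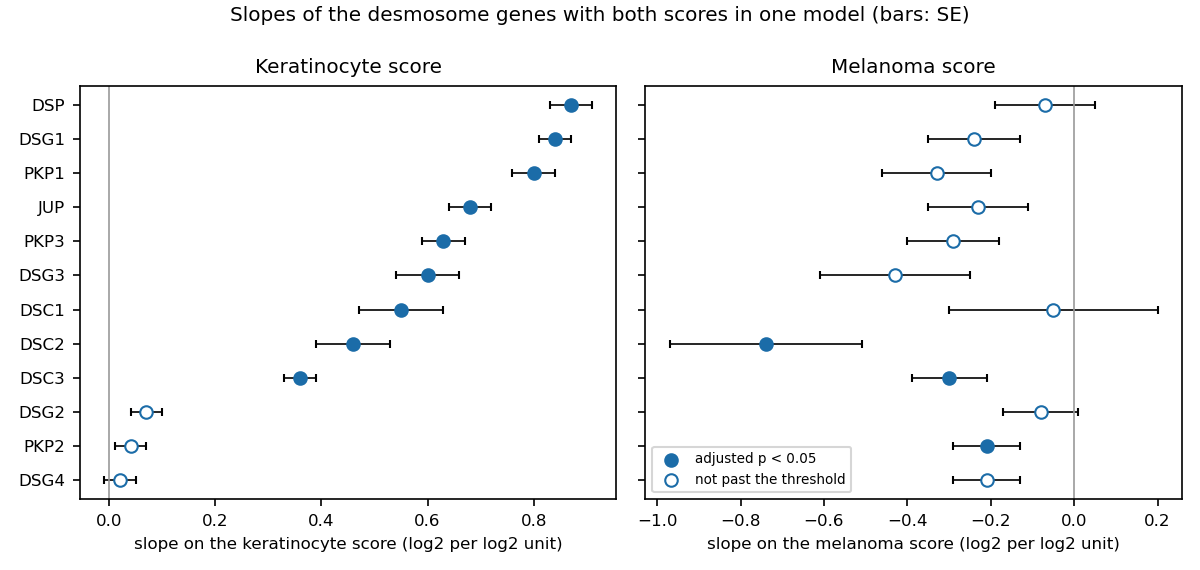
Slope of each of the 12 desmosome genes, in log2 per unit of the keratinocyte score and of the melanoma score, from a model with both scores and the slide part; points are estimates and bars standard errors over 48 regions. On the keratinocyte score the slopes run from 0.02 for DSG4 to 0.87 for DSP.

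Within sets, the correlation of the desmosome score with the keratinocyte score passed the threshold in sets A and B. The r values rest on different numbers of regions and ranges of score, so they do not rank the sets. Pearson's r was 0.95 over the 12 regions of set A (permutation p = 1e-05, the smallest the resamples give, adjusted p = 0.00126; Spearman's rho 0.94, p = 3e-05). Without the 2 regions farthest from the median it was 0.94. Regions of the other sets fell into separate clusters of keratinocyte score, and the clusters of 6 or more were tested apart. In the cluster of 8 regions of set B, r was 0.99 (exact permutation p = 4.96e-05, adjusted p = 0.00313; rho 0.98, p = 0.000397), and 0.97 without the 2 farthest regions. The clusters of 7 in set C (r = 0.79, exact permutation p = 0.0458, adjusted p = 0.167; rho 0.43, p = 0.354) and set D (r = 0.93, exact permutation p = 0.0115, adjusted p = 0.096; rho 0.86, p = 0.0238) did not pass. With the melanoma score, no cluster passed, the r in set A being -0.73 over 10 regions (permutation p = 0.0201, adjusted p = 0.112; rho -0.75, p = 0.0177) and -0.43 without the 2 farthest. Of 112 such relations computed with the keratinocyte score 15 passed, and of 140 with the melanoma score 6 passed. Regions of a set share tumours, so these permutation p-values are too small.

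**Figure D2:**
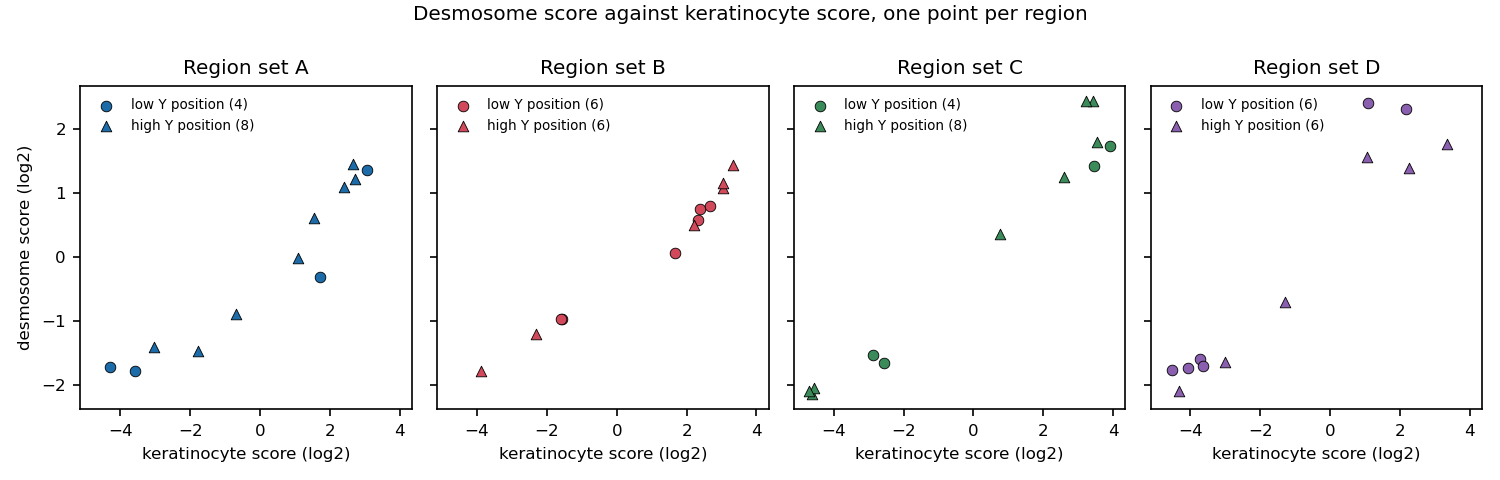
Desmosome score against keratinocyte score, both means of gene-centred log2 levels, for the 12 regions of each of the 4 sets. Points rise together in every set, with r = 0.95 over all 12 regions of set A.

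At a given keratinocyte score, 3 of the 12 desmosome genes fell with the melanoma score, 0 rose and 9 did not pass. DSC2 fell by 0.74 ± 0.23 (SE) log2 per unit (adjusted p = 0.0205), DSC3 by 0.30 ± 0.09 (adjusted p = 0.021) and PKP2, at the level of the background in most regions, by 0.21 ± 0.08 (adjusted p = 0.0454). DSP had a slope of -0.07 ± 0.12 (adjusted p = 0.695) and DSC1 of -0.05 ± 0.25 (adjusted p = 0.912). Adjusted over the list alone, 8 of the 12 passed. The 3 calls were lost in several alternatives, and not alike. With the background ratio as a covariate the median slope of the list shrank from -0.235 to -0.086. With background subtracted (limma) it was -0.246, and it was -0.211 without the low part of set A and -0.316 without the high part of set C, so there the calls ended while the slope did not shrink by much. TMM factors and DESeq2 called 1 each. The list test, camera, gave an adjusted p of 0.0355, with adjusted p = 0.58 with an estimated correlation. Without the high part of set C, the most deeply counted, the DSC2 slope was -0.742 with an adjusted p of 0.376. Regions share tumours, so the p-values of edgeR's quasi-likelihood test are too small here too.

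The next question was which other genes went with each cell type. With the keratinocyte score 1182 genes rose and 795 fell among 18560 tested, and with the melanoma score 881 rose and 2204 fell. Genes of epidermal differentiation and stress rose most steeply with the keratinocyte score: the antimicrobial S100A7 by 1.08 ± 0.10 log2 per unit, S100A9 by 1.03 ± 0.09, S100A8 by 1.02 ± 0.09 and the cornified-envelope precursor SPRR1B by 1.00 ± 0.08. The keratins KRT6A (1.07 ± 0.09) and KRT16 (0.99 ± 0.08) rose too, but keratins guided the choice of regions. SERPINE2 fell by 0.29 ± 0.05, MIA, secreted by melanoma cells, by 0.27 ± 0.04, A2M by 0.25 ± 0.06, S100A1 by 0.24 ± 0.06, APOD by 0.23 ± 0.04 and CDH19 by 0.23 ± 0.04. With the melanoma score, QPCT rose by 1.11 ± 0.09, CDK2, which lies next to PMEL, by 0.78 ± 0.08, MITF, the master regulator of melanocytes, by 0.73 ± 0.07, PRKD3 by 0.72 ± 0.08 and C11orf96 by 0.69 ± 0.10. PMEL rose by 1.30 ± 0.12 but guided the choice of regions. DEFB4B fell by 1.33 ± 0.32, TMSB4X by 0.82 ± 0.13, IGHG2 by 0.77 ± 0.19, ADAP2 by 0.55 ± 0.08, IL32 by 0.44 ± 0.12 and FAM241A by 0.44 ± 0.08. When parts were left out singly, the slopes nearest to 0 were -0.787 for DEFB4B, -0.235 for IGHG2, -0.276 for IL32 and -0.223 for FAM241A, and these did not pass. Over all regions the 24 slopes had adjusted p-values of 0.00736 or lower in edgeR's quasi-likelihood test, which are too small because regions share tumours.

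Lists of keratinocyte genes rose with the keratinocyte score. Of the measured members not in the score itself, 8 of 8 suprabasal genes rose (CALML5 by 0.95 ± 0.08, KRTDAP by 0.83 ± 0.06), with adjusted p = 1.28e-05 by camera with an estimated correlation. So did 20 of 22 cornified-envelope genes (FLG, filaggrin, by 0.95 ± 0.14; adjusted p = 0.00118 with an estimated correlation), 9 of 9 stress genes (0.00359) and 7 of 10 basal genes (COL17A1 by 0.71 ± 0.05, CDH3 by 0.29 ± 0.07; 0.000356). The desmosome list had an adjusted p of 1.07e-05 by the same test. Among the stress genes is KRT6A, and keratins guided the choice of regions. The score genes KRT5 and KRT14 belong to the basal list, and KRT1 and KRT10 to the suprabasal list. So a rise of the other genes of those lists was near to given. All 6 gap junction genes rose (GJB2 by 0.78 ± 0.07, GJA1 by 0.58 ± 0.03; adjusted p = 4.99e-05 with an estimated correlation), as did 6 of 10 adherens genes (NECTIN1 by 0.44 ± 0.04, CDH1 by 0.29 ± 0.05; 0.00749) and 4 of 10 tight junction genes (CLDN1 by 0.36 ± 0.04, CLDN4 by 0.26 ± 0.05; adjusted p = 0.0982 with an estimated correlation). Adjusted over the list alone, these counts were 8 suprabasal, 21 cornified, 9 stress, 9 basal, 6 gap junction, 8 adherens and 5 tight junction genes. CTNNB1 had a slope of -0.06 ± 0.02 (adjusted p = 0.0932) and TJP1 of -0.01 ± 0.02 (adjusted p = 0.907). Regions share tumours, so camera's p-values here are too small.

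Over the slide parts, each taken as 1 value, the same lists rose in 8 of 8 parts. The mean slopes were 0.80 ± 0.29 (SD) for stress, 0.69 ± 0.09 for suprabasal, 0.50 ± 0.09 for cornified-envelope, 0.43 ± 0.14 for gap junction, 0.31 ± 0.14 for basal, 0.13 ± 0.06 for adherens and 0.12 ± 0.08 for tight junction genes. Langerhans cell genes (0.09 ± 0.07) and appendage genes of sweat glands and ducts (0.08 ± 0.03) also rose in 8 of 8. Each of these lists had an exact sign-flip adjusted p of 0.034. Most Langerhans and appendage genes lay at the level of the background. With background subtracted no list passed on either score, the smallest adjusted p being 0.0547, as for the desmosome list, though all slopes that had passed kept their sign. With 8 parts, whether any list passes rests on how many lists reach the smallest p values. So this loss alone does not show weaker slopes. With area-normalized values the adherens, tight junction, Langerhans and appendage slopes did not pass either. Hypoxia and glycolysis genes had a slope of 0.13 ± 0.12 (exact adjusted p = 0.073), pigment cell genes -0.11 ± 0.08 (0.073) and targets of MAPK signalling -0.06 ± 0.04 (0.055).

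**Figure D3:**
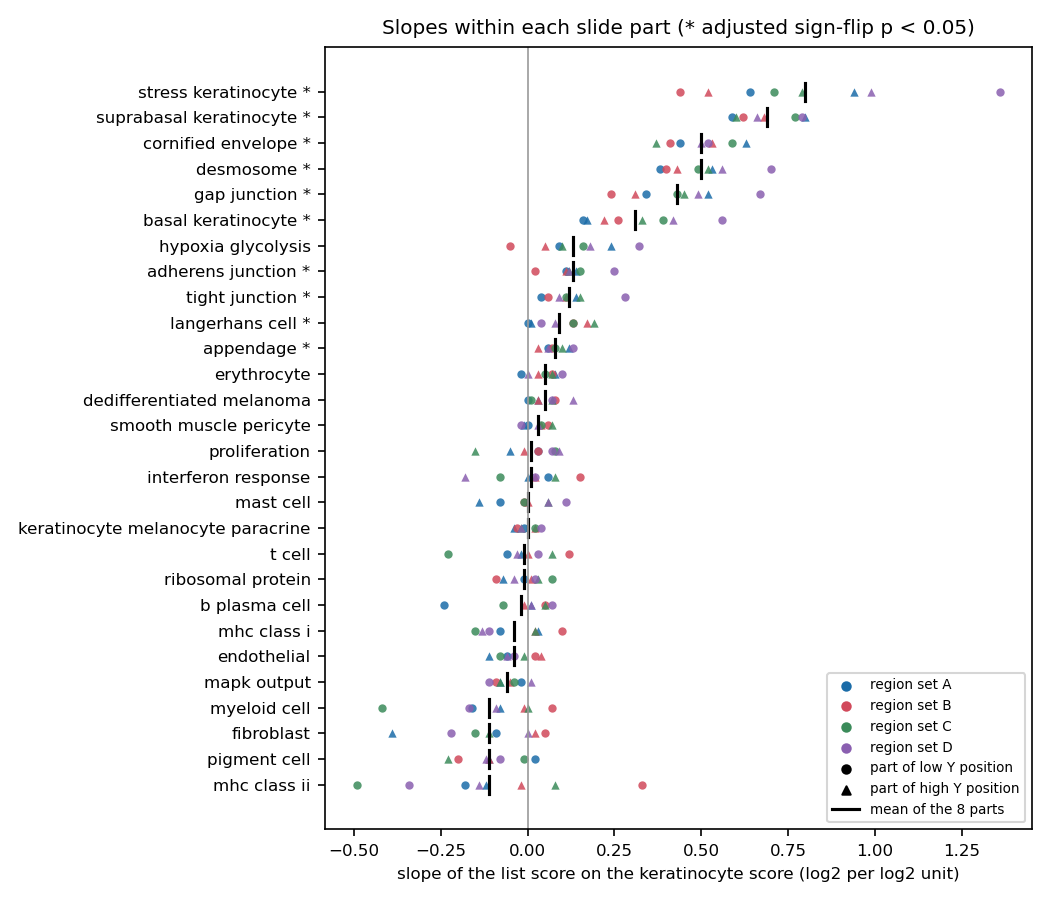
Slope of each gene list's score on the keratinocyte score in each of the 8 slide parts (points). On the keratinocyte score the means are 0.80 for stress, 0.69 for suprabasal and 0.50 for desmosome genes.

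Members of several immune and stromal lists fell with the keratinocyte score, though none of those lists held by camera with an estimated correlation. CD45 helped to guide where regions were placed, and its bearing on the immune lists was not tested. Of the lists, 10 of 13 myeloid genes fell (C1QB by 0.21 ± 0.04, CD68 by 0.14 ± 0.03; adjusted p = 0.0554 with an estimated correlation) and 6 of 10 MHC class II genes fell (HLA-DRB1 by 0.18 ± 0.06; adjusted p = 0.118 with an estimated correlation). There fell also 6 of 14 T cell genes (TRBC1 by 0.14 ± 0.03; adjusted p = 0.195 with an estimated correlation), 6 of 14 B and plasma cell genes (IGHG1 by 0.30 ± 0.06; 0.251), 6 of 18 pigment cell genes (0.211), 3 of 10 endothelial genes (ENG by 0.13 ± 0.02; 0.187) and 2 of 14 fibroblast genes (SPARC by 0.16 ± 0.05; 0.252). With the background ratio as a covariate 7 myeloid, 1 MHC class II, 6 T cell and 6 B and plasma cell genes were called, the median MHC class II slope going from -0.149 to -0.129. Without the low part of set C 2 myeloid genes were left, and the MHC class II and T cell calls were lost. Without the low part of set A 1 B and plasma cell gene was left, and without its high part 3 MHC class II genes. These are counts of calls, and a lost call need not mean a smaller slope. Of 12 MAPK targets, 4 fell, DUSP4 by 0.11 ± 0.03, and 2 rose (adjusted p = 0.153 with an estimated correlation). Hypoxia and glycolysis genes rose in 6 of 13 (LDHA by 0.12 ± 0.03; adjusted p = 0.11 with an estimated correlation). Fewer members passed in the lists of dedifferentiated melanoma (2 of 10 rose), Langerhans cells (2 of 4 rose), interferon response (2 of 21 rose, IFI27 by 0.34 ± 0.06, and 1 fell), smooth muscle (1 of 8 rose, NOTCH3 by 0.21 ± 0.03, and 1 fell), proliferation (1 of 23 rose and 1 fell), paracrine factors (1 of 12 rose, KIT by 0.09 ± 0.02, and 1 fell, EDNRB by 0.13 ± 0.04), mast cells (1 of 5 rose, KIT, which 2 lists hold) and appendages (1 of 9 rose, MUCL1 by 0.40 ± 0.06). By edgeR 0 of 10 MHC class I genes passed, with 2 at an unadjusted p under 0.05 and 1 called by DESeq2. Of the 4 erythrocyte and 14 ribosomal genes 0 passed by either tool, and 0 had an unadjusted p under 0.05 by edgeR. Regions share tumours, so edgeR's and camera's p-values are too small.

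With the melanoma score, 13 of 18 pigment cell genes rose and 0 fell (adjusted p = 4.09e-08 by camera with an estimated correlation), and over the slide parts their score rose by 0.55 ± 0.31 (SD), in 8 of 8 parts (exact adjusted p = 0.034, and past the threshold no longer with background subtracted). The 5 score genes came from this same list, and PMEL, which guided the choice of regions, is among the 18. So a rise of this list was near to given. Proliferation genes rose in 19 of 23 (PCNA by 0.50 ± 0.10, MCM4 by 0.40 ± 0.07, MCM5 by 0.33 ± 0.07, BIRC5 by 0.22 ± 0.06; adjusted p = 0.0325 with an estimated correlation). The median slope of that list was 0.337, but 0.065 without the high part of set C, and over the parts the mean was 0.09 ± 0.33, positive in 3 of 8 (exact adjusted p = 0.68). T cell genes fell in 9 of 14 (CD2 by 0.44 ± 0.09, CCL5 by 0.44 ± 0.13; adjusted p = 0.196 with an estimated correlation), as did B and plasma cell genes in 9 of 14 (IGKC by 0.88 ± 0.20; adjusted p = 0.196 with an estimated correlation), myeloid genes in 4 of 13 (0.58) and smooth muscle genes in 4 of 8 (ACTA2 by 0.36 ± 0.12; 0.28). With the background ratio as a covariate 7 proliferation, 3 T cell, 1 myeloid and 1 smooth muscle genes were called and the B and plasma cell calls were lost. With background subtracted (limma) the calls of these 4 immune and muscle lists were all lost. The median T cell slope was -0.332 in the fit over all regions, -0.245 with that covariate and -0.258 with background subtracted, so most T cell calls ended although the slope kept most of its size. For B and plasma cells it was -0.273, -0.1 and -0.154. Without the high part of set C, 1 T cell gene and 3 B and plasma cell genes were still called, and the myeloid and smooth muscle calls were lost. Over the parts, scores of B and plasma cells (-0.42 ± 0.54, positive in 0 of 8) and of Langerhans cells (-0.39 ± 0.26, 0 of 8) fell, each with an exact adjusted p of 0.034, though the first was 0.10 when the median over the list was used. Neither passed with area-normalized values or with background subtracted. Most Langerhans and T cell genes lay at the level of the background, and the bearing of placing regions by CD45 was not tested. The B and plasma cell mean leaned on the low part of set A, with a slope of -1.59, and was -0.254 without it. Part slopes were fitted on the melanoma score alone, so they do not hold the keratinocyte score fixed as the gene slopes do. Adjusted over the list alone, 21 proliferation, 14 pigment cell, 12 T cell and 10 B and plasma cell genes passed. EDNRB (0.73 ± 0.13), MC1R (0.49 ± 0.08) and KIT (0.48 ± 0.08), receptors through which keratinocytes act on melanocytes, rose among 12 paracrine genes, of which 1 fell, and 4 of 12 MAPK targets rose (DUSP4 by 0.51 ± 0.12, PHLDA1 by 0.41 ± 0.10; adjusted p = 0.074 with an estimated correlation). In the remaining lists, 3 of 10 tight junction genes fell (F11R by 0.40 ± 0.09, CLDN1 by 0.35 ± 0.12), 2 of 10 adherens genes rose (CTNNB1 by 0.32 ± 0.08) and 2 fell, and 2 each of 4 Langerhans, 9 appendage and 10 dedifferentiated melanoma genes fell. Of the interferon-response genes 1 rose (IFI6 by 0.68 ± 0.20) and 2 fell, of the mast cell genes 1 rose and 1 fell, and 1 gene fell in each of the basal, suprabasal, gap junction, endothelial (PLVAP by 0.24 ± 0.08) and MHC class II lists. By edgeR 0 genes passed in the cornified-envelope, stress, fibroblast and hypoxia lists, with 5, 3, 1 and 1 at an unadjusted p under 0.05 and 0, 0, 1 and 0 called by DESeq2. In the MHC class I, erythrocyte and ribosomal lists 0 genes passed by either tool, and 0 had an unadjusted p under 0.05 by edgeR. The stress list had a median slope of -0.43 although camera placed it upward (adjusted p = 0.942). With TMM factors 1 tight junction and 1 dedifferentiated melanoma gene fell, and 0 adherens and 0 appendage genes did. There 2 adherens genes still rose and 2 Langerhans genes still fell. Regions share tumours, so edgeR's and camera's p-values are too small.

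The balance of rising and falling genes moved with the scaling, and most melanoma-score calls were lost when a single part was left out. By TMM factors 1492 genes rose and 831 fell with that score, by DESeq2's Wald test 2019 rose and 695 fell, and without the high part of set C edgeR called 122 up and 46 down. A call can end without a smaller slope, as for DSC2 above. The keratinocyte-score genes divided into 1051 up and 1045 down by TMM, and into 1058 up and 1517 down by DESeq2.

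The last comparison was between the sets, the only grouping in the labels. Between them 12184 of 18560 genes differed (65.6%; edgeR's quasi-likelihood test), and set, slide and tumours cannot be told apart. Genes that differed included, higher, MGP and TGFBI in set D, NKX1-2 and IGHG1 in set A, CLEC1B in set B and HTRA1 in set C, and, lower, FLG in set D, IFI6 in set A, PI3 in set B and KLK6 in set C. Each is a difference of a whole set, and PI3 and KLK6 were also low in slide parts of other sets. Against the other sets 606 genes were higher and 267 lower in set A, 7620 and 1870 in set B, 2078 and 7469 in set C, and 1133 and 1049 in set D. This imbalance ran with the background: the upper quartile stood lowest over the negative probes in set B (2.07 times) and highest in set C (3.16 times). How far scaling to the upper quartile raised genes near background in set B and lowered them in set C was not tested. These p-values are too small because regions share tumours, and here they measure only the spread between regions. With counts summed per slide part edgeR called 0 genes, with 5429 at an unadjusted p under 0.05, while voom with the part as a random block called 3264. With the background ratio as a covariate 7211 were called, of which 5893 were among the 12184.

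Many of the genes with large differences between sets were high in a single slide part. In set D, MGP, an inhibitor of calcification, was 7.20 ± 0.57 (SE) log2 higher, with a level of 13.08 log2 CPM (counts scaled to a common total) in the low part and 4.99 in the high part. SERPINA3 was higher by 4.23 ± 0.40 (10.08 and 4.22), COL8A1 by 3.93 ± 0.38 (9.14 and 3.83) and the matrix protein TGFBI by 3.97 ± 0.33 (11.07 and 7.54). The secreted inhibitor PI3 (4.11 ± 0.70) and DEFB4B (4.09 ± 0.68) were higher too. The epidermal genes FLG (-4.09 ± 1.13) and LOR (-2.73 ± 0.81) were lower there, as was AP3B1 (-2.94 ± 0.74). In set A, NKX1-2 was higher by 4.40 ± 0.52 (9.57 in the high part and 4.68 in the low part), APOC2 by 2.58 ± 0.27 (6.88 and 6.08), and IGHG1 by 3.02 ± 0.45 (4.63 and 9.45), with IGKC, IGHG2 and IGHG4 at 2.69 ± 0.47, 2.34 ± 0.40 and 2.31 ± 0.40. The 4 immunoglobulin genes had negative values in DESeq2, -0.278 for IGHG1 and -0.655 for IGKC. IFI6 (-2.24 ± 0.49) was lower in set A. In set B, CLEC1B was higher by 4.68 ± 0.50 (9.97 in the low part and 4.79 in the high part) and ZP3 by 2.58 ± 0.39 (7.17 and 4.69), with TKTL1 (1.92 ± 0.31), MSC (1.74 ± 0.23) and ABCB5 (1.67 ± 0.27). Lower there, over the set, were PI3 (-3.82 ± 0.99), the gap junction gene GJB2 (-2.83 ± 0.88), S100A9 (-2.57 ± 1.03), ANXA1 (-2.38 ± 0.55) and DSC2 (-2.41 ± 0.72). None of these lay lower in both parts of set B than in all other parts. PI3 had 5.05 and 5.69 in set B, but also 5.75 and 5.36 in set A and 4.17 in the low part of set C. It had 10.07 in the high part of set C, and 9.49 and 11.21 in set D. DSC2 had 5.57 and 5.71 in set B, against 5.03 in the low part of set A. In set C, HTRA1 (2.64 ± 0.29), THBS2 (2.61 ± 0.37), LYZ (2.43 ± 0.48) and the cell cycle inhibitor CDKN2A (2.42 ± 0.29) were higher, and KLK6 (-2.23 ± 0.62), GAGE10 (-2.15 ± 0.43), BCAN (-1.67 ± 0.50) and CYTL1 (-1.67 ± 0.20) lower. LYZ had 10.46 in the low part of set C, but 5.30 in its high part, the lowest of all parts. HTRA1 had 6.05 in the low part of set C and 6.06 in the low part of set D, and THBS2 7.44 and 8.26. BCAN had 6.28 in the low part of set C, against 4.31 in the low part of set D. KLK6 had 5.02 in the low part of set C, against 4.78 in the low part of set A. CDKN2A, GAGE10 and CYTL1 lay beyond all other parts in both parts of set C. GAGE1, a near copy of GAGE10, had -2.08 ± 0.42, and whether their probes tell the copies apart is not stated. Both stood highest in the low part of set D (10.11 for GAGE10 and 10.06 for GAGE1), and without set D their differences were -1.31 and -1.24. Both parts of the set lay beyond all other parts for 15 of the 48 gene and set pairs named, where chance gives 3.6%, but the genes were chosen for size.

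**Figure D4:**
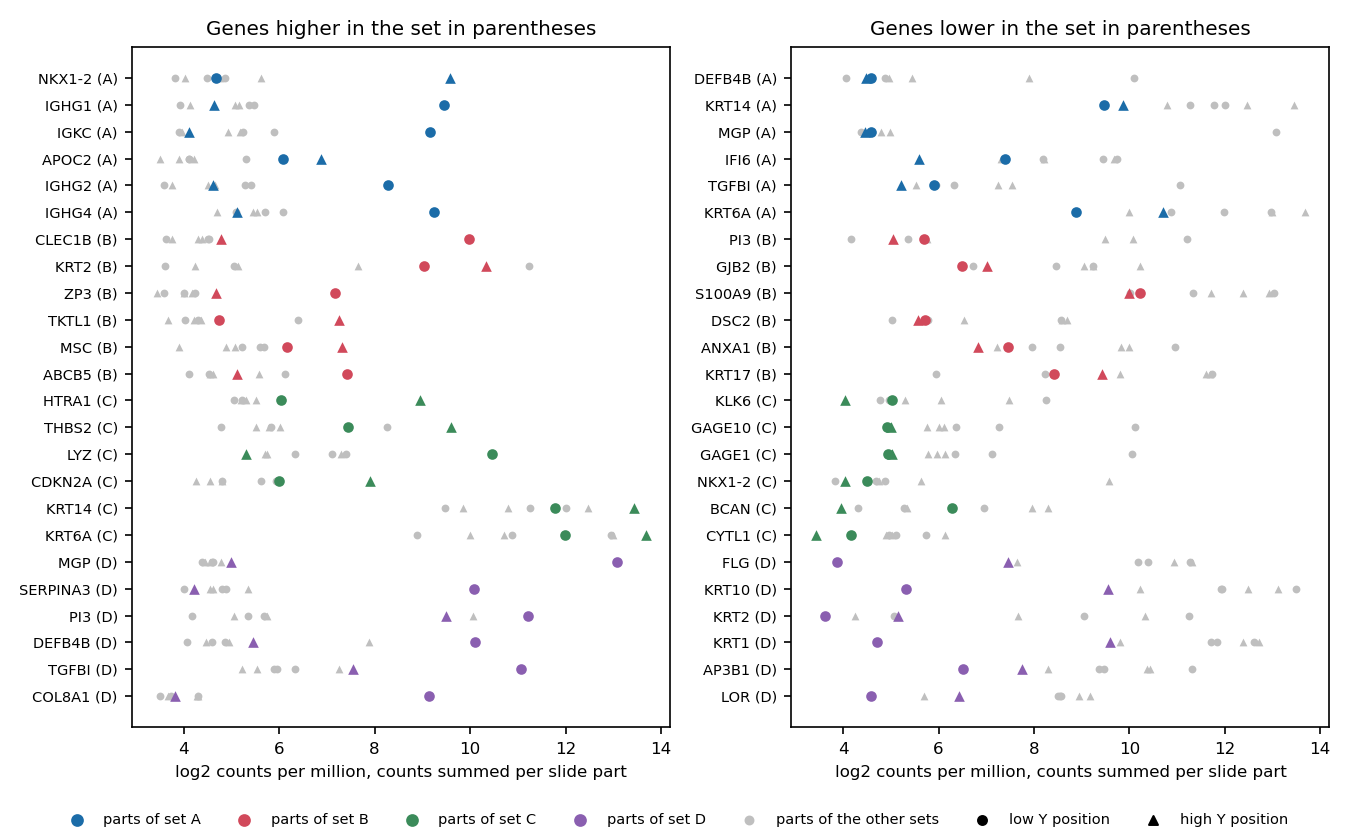
Level of the genes with the largest differences between sets, in log2 CPM of counts summed over each of the 8 slide parts, with the parts of the named set in colour. MGP reads 13.08 in the low part of set D and 4.99 in its high part.

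Among the desmosome genes 5 of 12 differed between sets by edgeR, DSG2, DSG3, DSG4, DSC2 and PKP2, and 5 passed adjusted over the list alone. DSC2 was 2.25 log2 higher in set D and 1.75 higher in set C, and DSG3 1.89 and 1.21 higher. In counts summed per part, DSC2 had 8.69 and 8.57 log2 CPM in the high and low parts of set D. In set C it had 8.58 in the high part but 5.78 in the low part. The high part of set A had 6.54, so the difference of set C lay in its high part. DSG4 (0.53 in set B) and PKP2 (0.36 in set B) lay above the limit of quantification in 0 and 3 of 48 regions, so their differences lie at the level of the background. By camera over regions the list as a whole was called in no set, with adjusted p-values of 0.303 for A, 0.466 for B, 0.268 for C and 0.56 for D. With counts summed per slide part camera called it in every set, down in A (adjusted p = 8.58e-08) and B (0.0143) and up in C (6.38e-06) and D (0.0231), while fry called it in none (0.579, 0.892, 0.604 and 0.807), nor over regions. Camera's directions are relative to all other genes. Over regions the members' median difference in log2 CPM was -0.189 in A, 0.263 in B, 0.434 in C and -0.407 in D. In B and D these medians ran against the direction camera gave on part sums. The gene differences given above are edgeR's fold changes, another measure. By edgeR most members were lower in B and higher in D, the directions camera gave. Camera on part sums also used the preset correlation between genes, while the estimate over regions was 0.647. So whether the list differed between sets, and in which direction, depended on the test and on the measure.

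Of 112 tests of a list in a set, camera called 27, fry 22, and camera 0 with an estimated correlation (9 at an unadjusted p under 0.05). With counts summed per slide part camera called 57 and fry 0 (9 at an unadjusted p under 0.05). List medians given here are of differences in log2 CPM, while values of single genes are edgeR's fold changes, so the measures differ. Ribosomal protein genes had a median difference of 0.64 log2 in set A, -0.87 in B and 0.47 in C, and adjusted p = 0.112, 0.112 and 0.478 with an estimated correlation. In set A the medians were -0.88 for MHC class I genes (HLA-B -1.53; adjusted p = 0.184 with an estimated correlation), -0.73 for interferon-response genes (IFI44L -1.88; 0.584), 0.61 for pigment cell genes (0.843) and 0.20 for MAPK targets (0.593). In set C they were 0.75 for hypoxia and glycolysis genes (ENO1 1.54, LDHA 1.35; adjusted p = 0.651 with an estimated correlation) and 0.47 for proliferation genes (PCNA 1.20; 0.584). In set D they were 0.35 for dedifferentiated melanoma genes (TNC 1.83; adjusted p = 0.112 with an estimated correlation), 0.65 for MHC class II (0.843), 0.79 for erythrocyte genes (HBA2 2.29; 0.184) and -0.69 for pigment cell genes (0.871). In set B fibroblast genes had a median of -0.59 (COL1A1 -1.74; 0.843) and MAPK targets -0.40 (DUSP4 -1.31; 0.212). Other camera calls, with their p values with an estimated correlation, were lower proliferation (median -0.22, adjusted p = 0.843), MHC class II (-0.63, 0.934), myeloid (-0.24, 0.939) and hypoxia genes (-0.31, 0.843) in set A. In set B they were lower adherens junction (-0.16, adjusted p = 0.681) and hypoxia genes (-0.42, 0.843), and in set C higher MHC class I (0.31, adjusted p = 0.934) and fibroblast genes (0.27, 0.843). In set D they were lower proliferation (-0.32, adjusted p = 0.939) and higher MHC class I (0.57, 0.75), myeloid (0.35, 0.843) and hypoxia genes (0.35, 0.843). The mast, Langerhans, T cell, B and plasma cell, endothelial, smooth muscle, appendage, paracrine, tight junction and gap junction lists, and the 4 keratinocyte lists, had no call in any set by camera over regions. Of these, fry over regions called the mast, Langerhans, T cell, B and plasma cell, endothelial, smooth muscle, appendage and paracrine lists in at least 1 set. Most of these fry calls were upward in set B, whose counts stood lowest over background. Among genes above the limit of quantification in 10% of regions were 2 of 5 mast, 1 of 4 Langerhans, 3 of 14 T cell and 2 of 9 appendage genes, so the calls of these 4 lists rest largely on genes at the level of the background. Of the other called lists, 7 of 14 B and plasma cell, 6 of 10 endothelial, 5 of 8 smooth muscle and 7 of 12 paracrine genes were among them. Camera on part sums called the mast, B and plasma cell, appendage, gap junction, basal, suprabasal and stress lists in at least 1 set. The p-values of camera and fry over regions are too small, because regions share tumours.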

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

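The tests of slopes between sets given here were all chosen after the data were seen, as were the tests of the background covariate between sets and of the region-level fit without the high part of set C. The other tests of explanations were set before their results were seen. Of 56 slopes of a list on a score tested for a difference between the 4 sets (permutation test over regions, adjusted p), 6 differed. Regions share tumours, so these p-values are too small. Basal keratinocyte genes rose with the keratinocyte score by 0.17, 0.23, 0.35 and 0.49 in sets A, B, C and D (adjusted p = 0.00056). The score itself holds KRT1 and KRT10, which had 4.70 and 5.32 log2 CPM in the low part of set D. In set D they lay above the limit of quantification in 7 and 6 of 12 regions. So the score may not span the same in every set, and how far this bears on the slopes was not tested. Mast cell genes had slopes of -0.11, -0.01, 0.04 and 0.08 on that score (adjusted p = 0.0069). The mast list rests largely on genes at the level of the background and shares KIT with the paracrine list. Hypoxia and glycolysis genes had 0.16, 0.02, 0.12 and 0.25 (adjusted p = 0.029). On the melanoma score, proliferation genes had slopes of 0.50, -0.05, 0.36 and -0.24 (adjusted p = 0.0014). MHC class I genes had -0.43, -0.19, 0.04 and 0.61 (adjusted p = 0.028), and MHC class II genes -0.42, -0.65, -0.10 and 1.04 (adjusted p = 0.019). Slopes within parts of the same set lay apart too. MHC class II genes had slopes of -0.08 in the high and -4.39 in the low part of set C. In set A they had 0.02 in the high and -0.88 in the low part. The low part of set C held 4 regions spanning 0.41 log2 of the melanoma score, against 8 and 4.12 in the high part. Its slope is therefore loosely fixed, and parts were not compared by a test. The tests between sets took no account of the spread between parts. So a difference between sets and one between single parts cannot be told apart.

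Proliferation genes rose with the melanoma score over regions, with a median slope of 0.337. None of 10000 random lists of the same level reached it (0 lists), so a rise shared by any genes of that level is argued against. With the background ratio as a covariate the median was 0.28, so background alone is argued against as well, although the members called went from 19 to 7. Without the deeply counted high part of set C the region-level median was 0.065, so that part may carry much of the rise. The mean slope over the other 7 parts was 0.054 against 0.092 over all 8, with 2 of 7 positive, which met neither outcome stated beforehand, and cell content, tumour and depth of that part stay open. Leaving out each part singly gave means of 0.0113 to 0.153. The steepest slope, 0.66, was in the high part of set A, so this mean leaned on other parts too.

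The sets differed in 12184 genes, and 1 of 90 random divisions of the regions, the real one, gave as many, the highest other giving 190, so chance can be excluded only in the sense of a random division of single regions. Those divisions broke up the slide parts, which the sets keep whole, so this does not show a difference between sets beyond one between parts, and with counts summed per part edgeR called 0 genes (5429 at an unadjusted p under 0.05, and voom with the part as a random block 3264). Pairing whole slide parts in the 5 other ways gave 6055 to 11835 genes, with a median of 7710, and 2 of the 5 came within 1.5 times of the real count, so how far the real grouping matters beyond the differences between parts stays open. Of the called genes 48.4% were still called with the background ratio as a covariate, which lies between the bounds stated for background as the whole cause and as excluded, so background and the sets cannot be told apart for the others. No biological explanation was tested, since the labels name no difference between the sets.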

How the results depend on the processing

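Alternatives on slide parts, background, saturation, estimated correlation and gene slopes were chosen after the data were seen. Of 17 alternatives for the 12184 genes between sets, 11 stayed within 1.5 times. The exceptions were 5018 without set B (leaving out each set gave 5018 to 11559), 0 with counts summed per slide part, 7211 with the background ratio as a covariate, 3264 with voom and the part as a random block, 5707 with background subtracted, and 5863 among the 11185 genes above the limit of quantification, where fewer genes were tested. Region number as a replicate block gave 11833, but the numbers are only an index: 72 pairs of same-numbered regions correlated from -0.49 to 0.46 (median 0.04), and 15 of 144 best matches had their own number. Of the 27 list calls, 0 held with an estimated correlation, and 57 were made on part sums. Relations past the threshold went from 15 to 6 with the median over the list and 9 of 56 without the 2 farthest regions for the keratinocyte score, and from 6 to 1 of 84 for the melanoma score. With each score alone, 7897 genes had a slope on the keratinocyte score and 10001 on the melanoma score. Melanoma-score genes numbered 1469 by limma on Q3 values, 538 with background subtracted, 668 with the background covariate, and 168 to 4124 when each part was left out, the lowest without the high part of set C. The desmosome slope over parts was 0.588 with background subtracted (adjusted p = 0.0547). Reversed were the B and plasma cell slope on the melanoma score (0.10 with the median over the list), IGHG1 (-0.278), IGHG2 (-0.0535), IGHG4 (-0.31) and IGKC (-0.655) by DESeq2, IGKC also by limma on Q3 values (-0.00173) and with background subtracted (-0.288), and KRT17 in set B (0.0543 with the random block, 0.0362 with background subtracted). The cause was not tested. Of 762 checks of named genes between sets 608 kept their side and direction, of 811 of gene slopes 756, of 728 of list slopes 700, and of 40 of the desmosome correlations 37. Alternatives for comparisons of region types, for their interaction with set, and for a region-type covariate, all named before the data were examined, were not run, since the tables used here name no types. DSG4, PKP2 and DSG2 lay above the limit of quantification in 0, 3 and 10 of 48 regions, and whether depth or absence of expression was the reason was not tested.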

Other observations

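Tests on matched and random lists in this part were chosen after the results were seen, and the other tests of explanations before. The keratinocyte score and the melanoma score varied together differently between slide parts. The correlation of the scores ranged from -0.91 in the low part of set B to 0.91 in the low part of set A, and the melanoma score spanned 4.12 log2 in the high part of set C against 0.41 in its low part. The keratinocyte score spanned 4.27 to 8.24 log2 in every part, so its slopes rest on a wider range than those on the melanoma score. IFI27, an interferon-response gene, rose with the keratinocyte score by 0.34 ± 0.06 log2 per unit (adjusted p = 9.93e-05 by edgeR, positive in 6 of 8 parts; regions share tumours, so p is too small), while IFI6 had a slope of 0.00 ± 0.05 on it.

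The rise of desmosome transcripts with the keratinocyte score was weighed against technical explanations. With the background ratio as a covariate the median gene slope was 0.502 against 0.575 without it. With area-normalized values, which use no quantile of the counts, the mean slope over the parts was 0.47 and positive in 8 of 8. None of 10000 random lists of the same level had a median slope as high (0 lists, highest 0.227). These values argue against background, scaling and level, and are consistent with the hypothesis that most desmosome transcripts in these regions come from keratinocytes, which the design does not test directly.

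At a given keratinocyte score, the median melanoma-score slope of the 9 desmosome genes that rose with the keratinocyte score was -0.29. Matched lists of genes with like keratinocyte slope and level gave -0.423 to -0.094, and the desmosome genes lay at percentile 44 of them. So the fall may be one that keratinocyte genes in general share, and a specific loss of desmosome transcripts near melanoma cells was not shown.

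The study's title links desmosomes with melanoma proliferation, so the hypothesis was tested that regions with lower desmosome transcripts at given keratinocyte and melanoma scores have higher proliferation scores. The partial correlation within slide parts was 0.168 over 48 regions (permutation p = 0.317), and leaving out each part gave -0.069 to 0.287. The value lay within the permutation spread, so a relation in either direction was neither shown nor excluded. The predicted negative relation with p under 0.05 was not seen. Desmosome mutations were not measured.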
